A study of Homo sapiens with 35 samples.

How the data were processed

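RNA was sequenced from Jurkat cells, a human T lymphoblast line, 24 h after treatment with water extracts of Bojungikki-tang (BJIKT, an herbal formula), of 4 of its herbs or of a mixture of those 4. Phosphate-buffered saline was the vehicle. The extracts were given at 500 or 125 µg/mL, and the mixture held 125 µg/mL of each herb. Per the labels, total RNA was made into directional mRNA libraries and read as 100 bp paired ends. The labels do not say whether the samples of a group were separate cultures, so each p-value measures the spread between samples only.

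The deposited table holds expected counts for 60675 Ensembl genes in 35 columns, 1 per library. The table has no header naming its unit. The unit was read from the values, of which 9.6% are not whole and none is negative, and from column totals that differ from library to library. The authors name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 and the builds hg38 and GRCh38, without the role of each tool. The annotation release, the strand setting and any filter were not given, so the levels of genes that overlap others, among them the antisense genes, carry that uncertainty. Totals ran from 24934447 to 35718561 counts per library.

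Libraries carry a description whose middle number runs from 1 to 3. These numbers are called sets here, and what they stand for is not stated. Set 1 held vehicle, BJIKT at both doses and ginseng at 500 µg/mL. Set 2 held ginseng at 125, astragalus at both doses and atractylodes at 500 µg/mL. Set 3 held atractylodes at 125, glycyrrhiza at both doses and the mixture. The vehicle was in set 1 alone, so for the 8 groups of sets 2 and 3 treatment and set cannot be told apart in a comparison with vehicle. The same holds for BJIKT against the mixture, and for the doses of ginseng and of atractylodes, which lie in different sets. The labels and the table hold 2 libraries of BJIKT at 500 µg/mL and 3 of each of the other 11 groups. The numbering of set 1 skips 1 library after those 2, and what it was is not stated.

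Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filterByExpr with the groups given, which left 17363. Factors were TMM, and 1 robust quasi-likelihood fit held all 12 groups, with 23 residual degrees of freedom, 15.3 prior degrees of freedom and a common biological coefficient of variation of 4.5%. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison are called. Counts of genes at an unadjusted p under 0.05 are given beside some results. With no change a share of 0.05 of the tested genes would reach it, so a count near that share shows no changes by itself. A fold change is given on the log2 scale with its standard error, and levels are CPM, counts scaled to a common library total with TMM factors, as mean ± SD. Each of the 11 treated groups was compared with vehicle, each extract at 500 with the same extract at 125 µg/mL, and BJIKT with the mixture at 500 µg/mL. The departure from additivity was the mixture's log2 change from vehicle minus the sum of those of the 4 herbs at 125 µg/mL. A dose by extract test asked, gene by gene, whether the change from 125 to 500 µg/mL differed between the 5 extracts.

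Before the data were examined, 41 gene lists with 952 genes, the comparisons, the alternatives and the rule for named genes were fixed. Of the lists, 40 had at least 3 tested members, and hepatocyte markers had 0. Lists share some members, such as SLC7A11 in the NRF2 and ATF4 lists and FTH1 in the NRF2 and iron lists. Lists were tested with camera of limma 3.58.1, 2-sided, at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, and p-values were adjusted over the 40 lists of a comparison. The named genes were those called, with a symbol, not pseudogenes, with a mean log2 CPM of at least 1 and every library of 1 group above every library of the other, taken by size of change, up to 12 per direction for BJIKT and the mixture at 500 µg/mL, 6 for each herb at 500 µg/mL and for BJIKT against the mixture, and 3 elsewhere. For the departure from additivity the separation of libraries was not asked. Up to 4 called members per called list, those with the smallest adjusted p, were added. The list members printed were picked from these after their values were seen, not all of them are printed, and 1 gene is not reported here. Symbols were found for 56558 of the 60675 gene IDs and positions in GENCODE 29 on GRCh38 for 57055.

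The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, only the compared groups in the fit, the replicate number as a block, each group against the mean of the other groups of its set, and leaving out each library in turn. Offsets for GC content and transcript length, which were available for 99.2% of tested genes, and the comparison within sets for gene lists were added after the data were seen. The fit was tested on simulated counts with independent genes and the dispersions of the data, 50 changed genes per fold. These changed genes were drawn from those with an average log2 CPM over 1, and no difference between sets was simulated. For BJIKT at 500 µg/mL against vehicle the fit called 86% of such genes changed 1.5-fold, 98% at 2-fold and 100% at 4-fold. For glycyrrhiza at 500 µg/mL these were 90%, 96% and 100%, and for the mixture 92%, 98% and 100%. At the smallest fold simulated, fitted at a median size of 0.33, 0.34 and 0.32 on the log2 scale, it called 76%, 82% and 80%. False calls were 11, 7 and 9 of 17136 unchanged genes. In each, the 1 list raised in the simulation was called and 0 of the others. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.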

Results

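Gene expression was measured by RNA sequencing in 35 libraries of Jurkat cells, a human T lymphoblast line, after 24 h with Bojungikki-tang (BJIKT, an herbal formula given as a water extract), with water extracts of 4 of its herbs, or with a mixture of the 4. The herbs were Panax ginseng, Astragalus mongholicus, Atractylodes japonica and Glycyrrhiza uralensis. BJIKT and each herb were given at 500 and at 125 µg/mL, and the mixture at 500 µg/mL in total. There were 3 libraries in each of 11 groups, vehicle among them, and 2 in the group of BJIKT at 500 µg/mL. Libraries held from 24934447 to 35718561 counts, and 17363 genes were tested. Counts of mitochondrially encoded genes took 6.51% of a library at the lowest and 8.95% at the highest, the latter in vehicle replicate 1. On the first principal component, with 7.27% of the variance, 10 of the 11 libraries of set 1 lay between -23.1 and -6.4, and ginseng replicate 1 at 500 µg/mL lay at 12.1. The 24 libraries of sets 2 and 3 lay between -1.1 and 11.7.

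**Figure D1:**
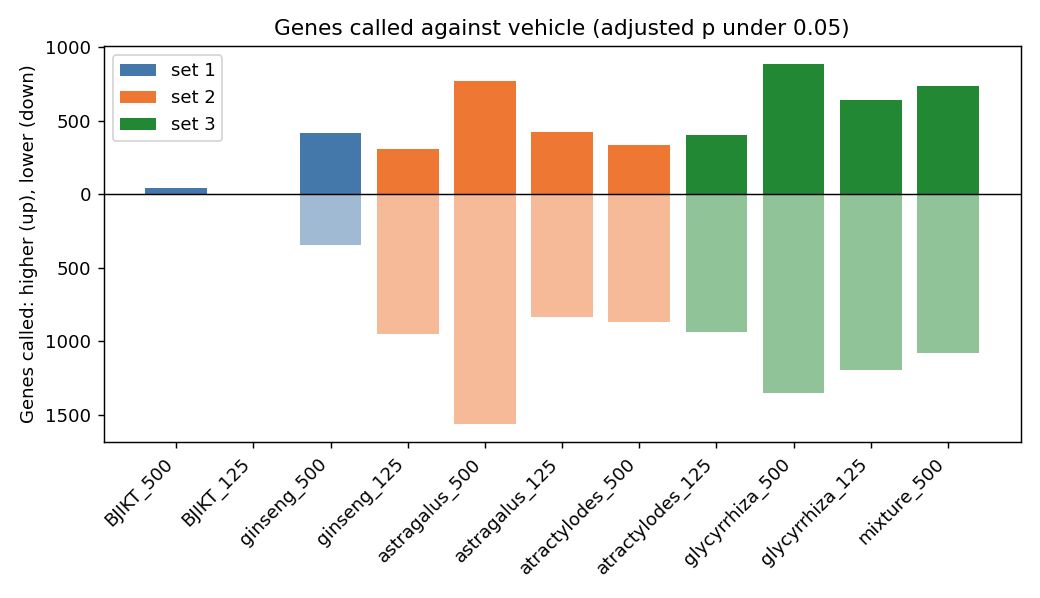
Number of genes called in each treated group against vehicle with edgeR, those higher drawn upward and those lower drawn downward in a paler shade, coloured by the set of the libraries. BJIKT had 47 genes at 500 µg/mL and 7 at 125 µg/mL, and the 8 groups of sets 2 and 3 had between 1203 and 2335.

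BJIKT at 500 µg/mL was compared with vehicle to ask what the whole formula changed in these T cells. Among the genes that rose were targets of NRF2, a regulator of the response to oxidants and electrophiles. OSGIN1, an oxidative stress induced gene on chromosome 16 (ENSG00000140961, 83948282 to 83966332 on GRCh38), rose 2.1-fold, by 1.07 ± 0.13 on the log2 scale, with adjusted p = 5.36e-06. SLC7A11, the cystine importer that feeds glutathione synthesis (ENSG00000151012, chromosome 4, 138164097 to 138242349), rose 1.8-fold, from 13.3 ± 0.834 CPM in vehicle (n = 3) to 24.0 ± 0.228 CPM (n = 2), by 0.85 ± 0.09 on the log2 scale. The ferritin heavy chain FTH1 rose 1.42-fold, thioredoxin reductase TXNRD1 1.33-fold, the quinone reductase NQO1 1.47-fold and glutathione reductase GSR 1.24-fold. Of 27 measured NRF2 targets, 10 rose and 0 fell over all genes tested, and 17 rose when adjusted over the list alone. Their median change was 0.22 on the log2 scale, with adjusted p = 2.61e-36 by camera.

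Chaperones of the endoplasmic reticulum rose with the same treatment. HSPA5, the main chaperone of its lumen (BiP), rose 1.29-fold, from 274.2 ± 15.1 to 355 ± 7.73 CPM, HSP90B1 1.2-fold and CANX 1.17-fold, and 6 of 25 members of the unfolded protein response list rose (13 adjusted over the list alone), with adjusted p = 4.58e-24. Of 37 ATF4 targets 3 rose (17 adjusted over the list alone), with PSAT1, an enzyme of serine synthesis, 1.27-fold higher and SLC3A2, the heavy chain of amino acid transporters, 1.16-fold higher, at adjusted p = 9.37e-24 for the list. The long noncoding RNAs LUCAT1, CYTOR, MIAT and MIR4435-2HG rose by 0.90, 0.55, 0.48 and 0.43 on the log2 scale, and CRIM1, BEST1 and KIAA0319 by 0.97, 0.80 and 0.52. DNTT, the polymerase that adds untemplated bases during receptor gene recombination, fell by 0.24 on the log2 scale.

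In all, 47 genes passed against vehicle with BJIKT at 500 µg/mL, 43 of them higher, and 11 lists passed with camera. Without a filter on low counts 114 of 199 called genes were higher. With only the compared groups in the fit 4 genes passed, and of the named genes OSGIN1, SLC7A11 and FTH1 kept their call. Against the other groups of set 1, which held treated cells too, 15 passed, 13 of them among the 47, and of the named genes OSGIN1, CRIM1, SLC7A11, FTH1, GSR and HSPA5 kept their call. With an estimated correlation 7 lists held, NRF2 targets (adjusted p = 3.71e-11), ATF4 targets, the unfolded protein response, SREBP2, iron, aryl hydrocarbon receptor and TFEB targets. Of 20 named genes, 7 kept their call whichever library was left out, namely OSGIN1, SLC7A11, FTH1, TXNRD1, GSR, HSPA5 and PSAT1. The other 13 lost it without BJIKT replicate 1, when 9 genes were called, and 11 of them also without replicate 2, when 13 were called, and the iron list lost its call without vehicle replicate 1, at a median of 0.01.

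BJIKT at 125 µg/mL gave changes of smaller size, led by chaperones. HSPA5 rose 1.22-fold, by 0.28 ± 0.04 on the log2 scale with adjusted p = 0.00351, and HSP90B1 and RCN2, a calcium-binding protein of the endoplasmic reticulum, rose 1.2-fold each. FHIP2B, SNHG3 and GFOD1 fell by 0.26, 0.25 and 0.21 on the log2 scale. Of 25 unfolded protein response genes 2 rose (8 adjusted over the list alone), with adjusted p = 2e-08, and of 27 NRF2 targets 0 rose over all genes and 5 over the list alone, with adjusted p = 0.000707. These were the 2 of 10 called lists that held with an estimated correlation, each with adjusted p = 0.00423. Against the other groups of set 1 the NRF2 list turned, at a median of -0.045 that passed camera's test. Those groups held BJIKT and ginseng at 500 µg/mL beside vehicle, so a rise with dose would give this turn too. Of the 6 named genes, 0 kept their call whichever library was left out. The count of 7 genes, 4 of them higher, was 0 without vehicle replicate 1, 160 without vehicle replicate 2, 1 without vehicle replicate 3, and 53, 3 and 0 without BJIKT replicates 1, 2 and 3 in turn. DESeq2 called 168.

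Raising BJIKT from 125 to 500 µg/mL, both in set 1, raised 11 genes and lowered 0. SLC7A11 rose 1.45-fold, by 0.53 ± 0.09 on the log2 scale with adjusted p = 0.00294, FTH1 1.37-fold, OSGIN1 1.53-fold, CHAC1, an enzyme that breaks down glutathione, 1.46-fold and GSR 1.16-fold. Of the 27 NRF2 targets 4 rose (10 adjusted over the list alone), with a median of 0.16 and adjusted p = 6.48e-21. ATF4 targets had 2 of 37 higher (10 adjusted over the list alone). The S phase list had a median of -0.06 with 0 of 34 members called, and held with an estimated correlation at adjusted p = 0.03. Of 14 called lists 7 held so. Heat shock genes (median -0.05, mean 0.02) and aryl hydrocarbon receptor targets (median 0.11, mean -0.01) differed in sign between median and mean, and their calls were lost, at adjusted p = 0.0579 and 0.0905 with an estimated correlation. The 11 genes became 0 without either BJIKT library at 500 µg/mL and 3 without any 1 of those at 125 µg/mL, and DESeq2 called 16, of which 14 were higher. Of the genes called without a filter 70 of 135 were higher, and 2 of 4 with only the compared groups in the fit.

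The mixture of the 4 herbs at 500 µg/mL, in set 3, was compared with vehicle in set 1, to set the herbs together against the whole formula. The oxidant response genes rose here as well, with OSGIN1 2.15-fold higher (1.11 ± 0.12 on the log2 scale, adjusted p = 9.99e-08), SLC7A11 1.97-fold higher (26.2 ± 0.862 CPM, n = 3, against 13.3 ± 0.834), NQO1 1.51-fold and TXNRD1 1.38-fold higher. Of 27 NRF2 targets 11 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.17 and adjusted p = 2.95e-10, which held with an estimated correlation. ATF4 targets (8 of 37 higher, 12 higher and 1 lower adjusted over the list alone) and the unfolded protein response (6 higher and 1 lower of 25, 8 and 1 adjusted over the list alone, among them HSPA5 and SEL1L by 0.27 and 0.24 on the log2 scale) also held. LUCAT1, CRIM1, MIAT, IFI44 and OSBPL10 rose by 1.15, 0.90, 0.77, 0.74 and 0.71 on the log2 scale.

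Some members of the T-lineage and Notch lists were lower with the mixture than in vehicle, and neither list held with an estimated correlation. The T-lineage transcription factors TCF7 and GATA3 fell by 0.42 and 0.37 on the log2 scale, and the receptors NOTCH1 and NOTCH3 by 0.36 and 0.56. Of 24 T-lineage factors 7 fell and 0 rose (8 fell adjusted over the list alone), at adjusted p = 0.000138 by camera and 0.234 with an estimated correlation. Of 14 Notch targets 6 fell (6 adjusted over the list alone), at adjusted p = 0.000138 and 0.23 with an estimated correlation. CAMK2N2, PRR36, CLIP3, ADGRG1, OTX1 and SRCAP fell by 0.75, 0.69, 0.53, 0.52, 0.55 and 0.54 on the log2 scale, the clock repressor NR1D1 by 0.54 and the immediate early factor EGR1 by 0.59. In all, 1817 genes passed, 737 higher and 1080 lower, and 3 of 13 called lists held with an estimated correlation. The count was 577 without vehicle replicate 1 and 643 without mixture replicate 3, when EGR1 lost its call at -0.39 and -0.53. In edgeR 0 genes passed against the mean of the other groups of set 3, with 812 at an unadjusted p under 0.05. Those groups held atractylodes at 125 µg/mL and glycyrrhiza at both doses, herbs of the mixture, so effects of these herbs would cancel there too. Against that mean the ATF4 list turned, at a median of -0.04 that passed camera's test, the T-lineage and Notch lists had medians of 0.02 and 0.01, and NOTCH1, NOTCH3, TCF7, GATA3, EGR1, PRR36 and ADGRG1 differed by 0.06, 0.04, 0.02, 0.01, 0.06, 0.03 and 0.03 on the log2 scale.

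**Figure D2:**
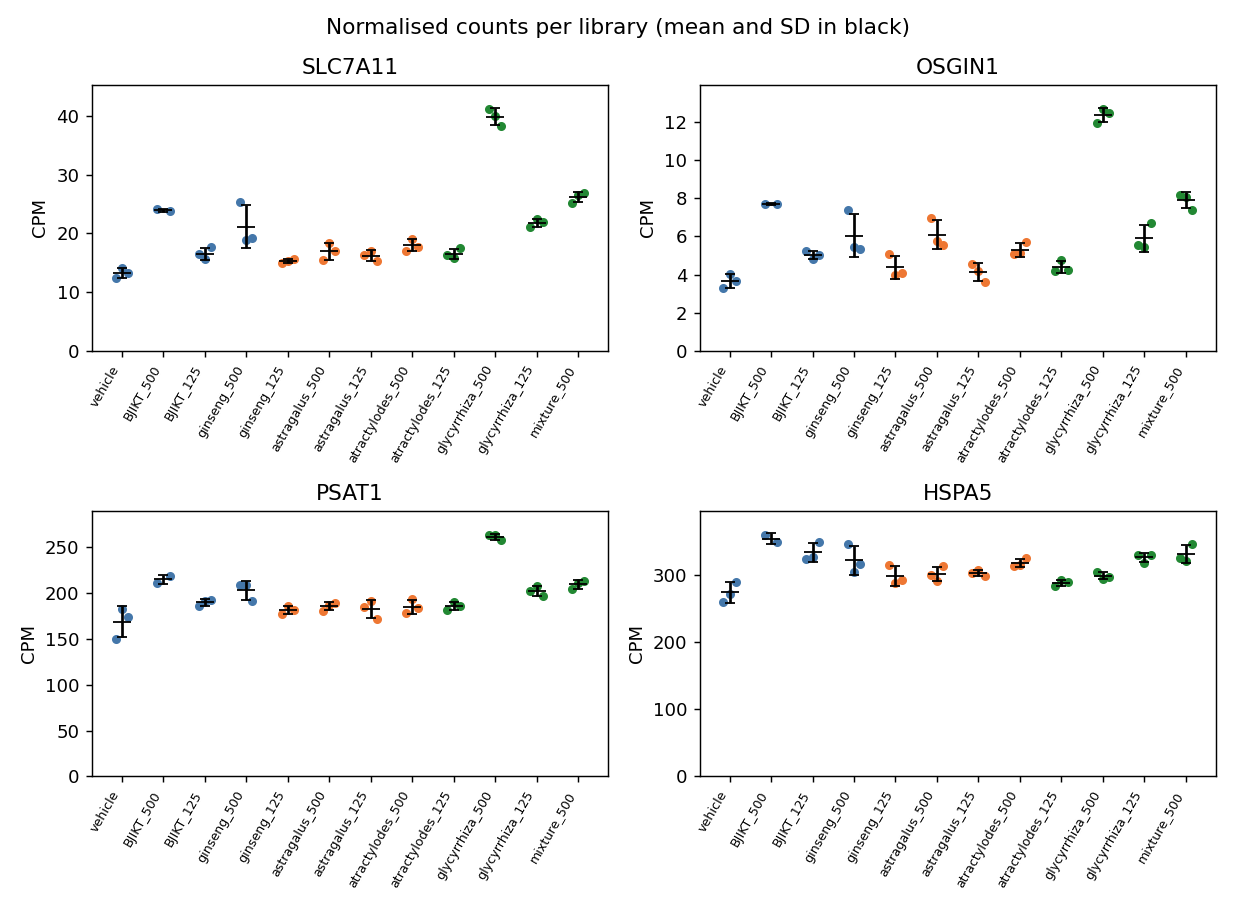
Level in CPM of SLC7A11, OSGIN1, PSAT1 and HSPA5 in each of the 35 libraries, as points coloured by set, with the mean and SD of each group in black. SLC7A11 has its highest mean, 39.9 CPM, in glycyrrhiza at 500 µg/mL, against 13.3 CPM in vehicle.

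Glycyrrhiza at 500 µg/mL, in set 3, gave the largest changes from vehicle of the 11 treated groups in OSGIN1, SLC7A11 and the median of the NRF2 list. OSGIN1 rose 3.37-fold, by 1.75 ± 0.11 on the log2 scale, from 3.66 ± 0.383 to 12.4 ± 0.375 CPM (n = 3 each), SLC7A11 3-fold, from 13.3 ± 0.834 to 39.9 ± 1.44 CPM, NQO1 1.94-fold and FTH1 1.59-fold. Of 27 NRF2 targets 17 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.27 and adjusted p = 3.58e-31. Amino acid stress genes rose with them, 25 of 37 ATF4 targets (26 adjusted over the list alone) with a median of 0.24 and adjusted p = 1.06e-38, among them the lipoprotein receptor VLDLR and PSAT1, 1.58-fold and 1.55-fold higher. Cholesterol synthesis genes rose too, 17 of 26 with 2 lower (19 and 2 adjusted over the list alone), at adjusted p = 5.3e-13, with HMGCS1 1.36-fold higher. These 3 lists of 13 held with an estimated correlation.

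Some members of the Notch, S phase and G2 and M phase lists were lower with glycyrrhiza at 500 µg/mL than in vehicle, and none of these lists held with an estimated correlation. NOTCH3 fell by 0.82 ± 0.09 on the log2 scale, from 138 ± 12.8 to 78.2 ± 2.37 CPM, PTCRA, the pre-T-cell receptor alpha chain, by 0.76, ADGRG1 by 0.81, NOTCH1 by 0.47 and TCF7 by 0.49. Of 14 Notch targets 7 fell (9 adjusted over the list alone), at adjusted p = 1.51e-07 by camera and 0.0751 with an estimated correlation. Of 34 S phase genes 10 fell (11 adjusted over the list alone), MCM2 of the replicative helicase among them by 0.24, at adjusted p = 0.000158 and 0.132 with an estimated correlation. Of 42 genes of G2 and M phase 9 fell (9 adjusted over the list alone), with the mitotic kinase PLK1 lower by 0.40 on the log2 scale, at adjusted p = 0.00167 and 0.336 with an estimated correlation, and lost its call without vehicle replicate 2, at a median of -0.02. LUCAT1, CRIM1, GPNMB and MIAT rose by 1.63, 1.39, 1.04 and 1.03. In all, 2237 genes passed, 885 higher and 1352 lower, and 22 of 23 named genes kept their call whichever library was left out. The count was 1195 without vehicle replicate 1, when FA2H lost its call, and 1213 without glycyrrhiza replicate 1. Against the mean of the other groups of set 3, which held treated cells too, 187 genes passed, 138 of them higher. Of the 187, 154 were among the 2237, OSGIN1, SLC7A11, FTH1, PSAT1, NOTCH3 and PTCRA included. NOTCH1, TCF7, MCM2, PLK1 and FA2H lost their calls there, at -0.09, -0.07, -0.10, -0.08 and -0.29 on the log2 scale.

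Between the 2 doses of glycyrrhiza, both in set 3, targets of ATF4 and NRF2 were among the genes that rose. SLC7A11 rose 1.83-fold, by 0.87 ± 0.07 on the log2 scale with adjusted p = 1.14e-10, OSGIN1 2.1-fold, CHAC1 1.64-fold, FTH1 1.54-fold, VLDLR 1.47-fold, SESN2, a stress-induced inhibitor of growth signalling, 1.37-fold and PSAT1 1.29-fold. Of 37 ATF4 targets 16 rose (26 adjusted over the list alone), with a median of 0.20, and of 27 NRF2 targets 7 rose (16 adjusted over the list alone), with a median of 0.17. Cholesterol genes had 3 of 26 higher (16 adjusted over the list alone), MVD and EBP among them by 0.23 and 0.22 on the log2 scale. The recombinase genes RAG1 and RAG2 fell by 0.38 and 0.28 on the log2 scale, RAG1 from 56.6 ± 3.92 to 43.5 ± 2.17 CPM, and the vitamin A receptor STRA6 by 0.45. EGR1 rose by 0.79 on the log2 scale and GABARAPL1, an autophagy protein, by 0.34. At 125 µg/mL EGR1 was lower than in vehicle by 0.94, so its rise started from below the vehicle level. S phase genes (5 lower of 34 adjusted over the list alone, 0 over all genes) had a median of -0.07 and held with an estimated correlation at adjusted p = 0.00769. In all, 60 genes passed, 52 higher and 8 lower, and 10 of 13 called lists held with an estimated correlation. Without a filter on low counts 115 of 188 called genes were higher, and 139 of 209 with only the compared groups in the fit. Heat shock genes had a median of -0.06 and a mean of 0.03. The count of 60 became 39 without glycyrrhiza replicate 2 at 500 µg/mL, when EBP lost its call at 0.18. STRA6 lost its call without any 1 of the 6 libraries (-0.48 to -0.43), EGR1 without replicates 1 or 3 at 500 or 2 or 3 at 125 µg/mL (0.67 to 0.79), and RAG2 without replicate 3 at 500 or 1 or 2 at 125 µg/mL (-0.28 to -0.23).

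**Figure D3:**
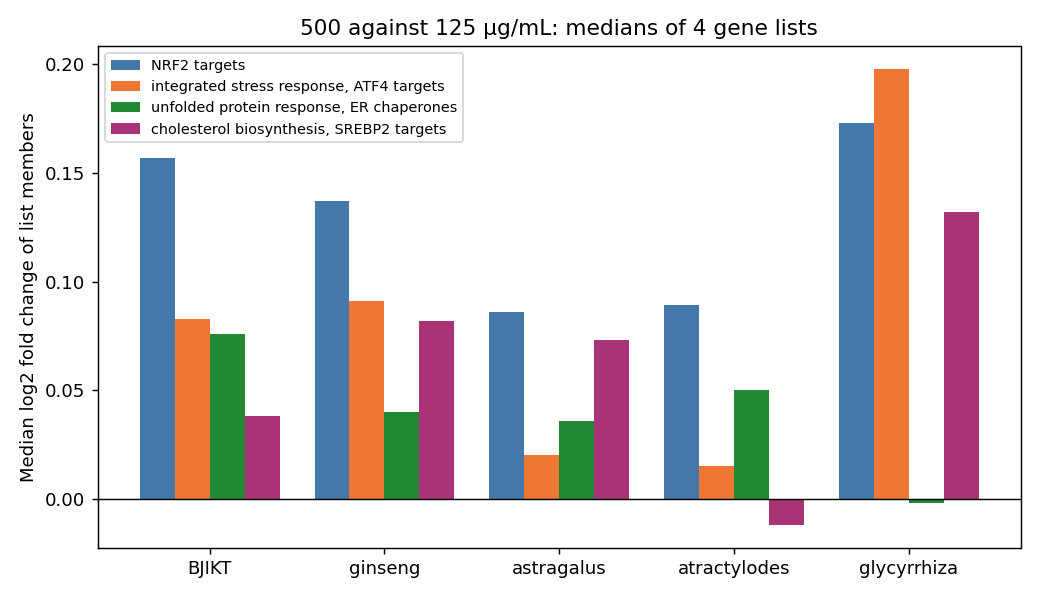
Median log2 fold change of the members of 4 gene lists (bars) between 500 and 125 µg/mL, for each of the 5 extracts. The NRF2 medians are 0.157, 0.137, 0.086, 0.089 and 0.173, in the order BJIKT, ginseng, astragalus, atractylodes and glycyrrhiza.

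Ginseng at 500 µg/mL, in set 1 with the vehicle, raised 9 of 27 NRF2 targets. SLC7A11 rose 1.6-fold, by 0.68 ± 0.08 on the log2 scale, and TXNRD1 1.34-fold. The list (12 higher and 1 lower adjusted over the list alone) had adjusted p = 1.93e-09, which held with an estimated correlation. Of 24 glycolysis genes 7 rose (8 adjusted over the list alone), with the lactate exporter SLC16A3 1.35-fold and the enolase ENO1 1.17-fold higher, at adjusted p = 0.000294 by camera and 0.0546 with an estimated correlation, and the call was lost without ginseng replicate 2, at a median of 0.06. Of 13 mitochondrially encoded genes 1, MT-ATP8, fell (1 adjusted over the list alone), by 0.79, and the list had a median of -0.13, at adjusted p = 0.0122 and 0.56 with an estimated correlation. Without vehicle replicate 1 both calls were lost, at -0.49 and a median of 0.01, whose sign is turned. Of 69 ribosomal protein genes 10 rose (24 adjusted over the list alone), with RPL23 1.28-fold higher, at adjusted p = 1.88e-13 and 0.271 with an estimated correlation. TCF7 and GATA3 fell by 0.31 and 0.32 on the log2 scale and NOTCH3 by 0.37. OSGIN1, NQO1 and LUCAT1 rose by 0.72, 0.56 and 0.80, and PRR36, NHERF2 and CMTM1 fell by 0.57, 0.45 and 0.51. In all, 762 genes passed, 415 higher and 347 lower, and 4 of 11 called lists held. With GC and length offsets 222 of 466 were higher, and 1 of 6 with only the compared groups in the fit. The count of 762 became 3 without vehicle replicate 1 and 4 without ginseng replicate 1, when 20 of the 22 named genes lost their call and SLC7A11 and TXNRD1 kept it. It was 1987 without vehicle replicate 2 and 1781 without ginseng replicate 2.

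Between the doses of ginseng, which lay in sets 1 and 2, SLC7A11 was 1.39-fold higher at 500 µg/mL, by 0.47 ± 0.08 on the log2 scale with adjusted p = 0.0102. ALDOC, a glycolytic aldolase, was 1.31-fold higher, by 0.39 ± 0.07 with adjusted p = 0.0133. These were the 2 genes called in the main fit. With only the compared groups in the fit both lost their call, at 0.46 and 0.38, and 3 other genes passed, 0 of them higher. DESeq2 called 12, and 209 passed without a filter, these 2 among them in each. Glycolysis (1 of 24 higher, 7 adjusted over the list alone), hypoxia-inducible factor targets (0 of 26, 10 over the list alone), cholesterol synthesis (0 of 26, 4 over the list alone), ATF4 targets (1 of 37, 5 over the list alone) and NRF2 targets (1 of 27, 8 over the list alone) were higher at 500 µg/mL. Those 5 of 16 called lists held with an estimated correlation, with adjusted p from 8.74e-08 for NRF2 to 0.000706 for cholesterol. The count was 456 without ginseng replicate 1 at 500 µg/mL, 1 without replicate 2 at 500 µg/mL, when ALDOC lost its call, and 0 without replicate 1 at 125 µg/mL.

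Astragalus at 500 µg/mL, in set 2, had 2335 genes called against vehicle, 771 higher and 1564 lower. PRR36 fell by 0.79 on the log2 scale. SRCAP, a chromatin remodeller, HCFC1, a chromatin cofactor, POLR2A, the largest subunit of RNA polymerase II, the ubiquitin ligase HUWE1 and the endocytic receptor LRP1 fell by 0.68, 0.66, 0.64, 0.64 and 0.65 on the log2 scale. OSGIN1, LUCAT1 and FGGY rose by 0.73, 0.81 and 0.56, and TXNRD1 by 0.31. Of 27 NRF2 targets 8 rose and 1, the transporter ABCC1, fell (10 and 1 adjusted over the list alone), at adjusted p = 0.0113 by camera and 0.106 with an estimated correlation. Of 24 T-lineage factors 10 fell (13 adjusted over the list alone), TCF7 by 0.40, at adjusted p = 1.44e-05 and 0.274 with an estimated correlation. Of 14 Notch targets 5 fell (6 adjusted over the list alone), NOTCH1 and NOTCH3 by 0.50 and 0.54, at adjusted p = 0.00626 and 0.529. Of 14 clock genes 5 fell and 1 rose (5 and 1 adjusted over the list alone), PER2 by 0.33, at adjusted p = 0.0185 and 0.274. Of the 8 called lists 0 held with an estimated correlation. Against the mean of the other groups of set 2, astragalus at 125 µg/mL among them, 1 gene passed. The count against vehicle was 1240 without astragalus replicate 3 and 1070 without vehicle replicate 1. Without vehicle replicate 1 the NRF2, Notch and clock lists lost their calls at medians of 0.11, -0.05 and -0.06.

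Atractylodes at 500 µg/mL, in set 2, had 1203 genes called against vehicle, 333 higher and 870 lower. SLC7A11 rose 1.35-fold, by 0.44 ± 0.08 on the log2 scale, TXNRD1 by 0.32 and HSPA5 by 0.21. EGR1 fell by 0.98 ± 0.17 on the log2 scale, the phosphatase DUSP1 by 0.38, the antiviral membrane protein IFITM3 by 0.59 and GATA3 by 0.42. Of 27 NRF2 targets 4 rose and 1 fell (6 and 1 adjusted over the list alone), at adjusted p = 0.00734 by camera and 0.091 with an estimated correlation. Of 18 early T-cell activation genes 2 fell (4 adjusted over the list alone), at adjusted p = 0.00375 and 0.104. Of 24 T-lineage factors 9 fell (11 adjusted over the list alone), at adjusted p = 0.000118 and 0.206, and against the other groups of set 2 their median turned to 0.02. Of the 12 called lists 0 held with an estimated correlation. Against the mean of the other groups of set 2, 2 genes passed, and the count against vehicle was 488 without vehicle replicate 1 and 371 without atractylodes replicate 2. OSGIN1, higher by 0.53, lost its call without vehicle replicate 1, at 0.46.

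At 125 µg/mL the herbs of sets 2 and 3 shared lower levels of a group of genes relative to vehicle. PRR36 fell by 0.64, 0.64 and 0.75 on the log2 scale with ginseng, atractylodes and glycyrrhiza, EGR1 by 0.78, 0.87 and 0.94 with astragalus, atractylodes and glycyrrhiza, and SRCAP by 0.55 and 0.58 with ginseng and atractylodes. Against the other groups of their set PRR36 turned to 0.07 and 0.10 with ginseng and atractylodes and SRCAP to 0.06 with ginseng, none of them called. With glycyrrhiza at 125 µg/mL SLC7A11 rose 1.64-fold (21.8 ± 0.671 CPM, n = 3), OSGIN1 1.6-fold and HSPA5 1.19-fold, TCF7 fell by 0.43, and NRF2 targets (8 higher and 1 lower of 27, 9 and 2 adjusted over the list alone) held with an estimated correlation at adjusted p = 0.00397. Against the other groups of set 3 that list turned, at a median of -0.05 that passed camera's test, with SLC7A11 at -0.24 and OSGIN1 at -0.36, neither called. Those groups held glycyrrhiza at 500 µg/mL and the mixture, so a rise with dose would give this turn too. LINC00861 rose by 0.85 with atractylodes and CFAP70 by 0.72 with glycyrrhiza. SPDYE6, a member of a family of near-identical genes, rose by 0.92, 1.02 and 0.89 with astragalus, atractylodes and glycyrrhiza, and POLR2J2 by 0.75 with atractylodes. Reads of such families can be assigned to the wrong member.

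The numbers of genes called at 125 µg/mL against vehicle were 1257 for ginseng (307 higher), 1256 for astragalus (420 higher), 1337 for atractylodes (401 higher) and 1836 for glycyrrhiza (639 higher). With only the compared groups in the fit they were 597 (40 higher), 38 (8 higher), 1009 (224 higher) and 1104 (232 higher). Against the mean of the other groups of their set, edgeR called 0, 0, 70 and 0, with 540, 720, 1271 and 581 at an unadjusted p under 0.05. For astragalus and glycyrrhiza those groups held the same herb at 500 µg/mL. Of the named genes, 1 of 6, 0 of 6, 3 of 6 and 9 of 10 kept their call whichever library was left out. Without vehicle replicate 1 the counts against vehicle were 243, 417, 589 and 628. For ginseng it was also 1896 without vehicle replicate 2, and 285 and 791 without ginseng replicates 2 and 3. For astragalus it was also 730 without vehicle replicate 3, and 163, 167 and 1968 without astragalus replicates 1, 2 and 3. For atractylodes it was also 658 and 603 without atractylodes replicates 2 and 3, and for glycyrrhiza 815 and 1076 without glycyrrhiza replicates 2 and 3.

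Between 500 and 125 µg/mL no gene passed for astragalus or atractylodes in edgeR's main fit, with 912 and 856 genes at an unadjusted p under 0.05, and DESeq2 called 0 and 3. Those 912 and 856 lie near the share of 0.05 of the 17363 tested genes that no change would give. With only the compared groups in edgeR's fit 3 and 18 passed, and 115 and 140 without a filter on low counts. By camera 9 lists were called for astragalus and 5 for atractylodes, of which 2 and 1 held with an estimated correlation. Whichever library was left out, 2 of 9 lists kept their call for astragalus and 4 of 5 for atractylodes. NRF2 targets had a median of 0.09 for both, with 0 of 27 members called over all genes and 4 and 1 adjusted over the list alone, and held with an estimated correlation at adjusted p = 0.000144 for astragalus and 2.57e-05 for atractylodes. Cholesterol synthesis genes had a median of 0.07 for astragalus, with 0 of 26 called (3 adjusted over the list alone), and held at adjusted p = 0.00576. The doses of astragalus share set 2, while those of atractylodes lie in sets 2 and 3. SLC7A11 differed by 0.07 ± 0.08 and 0.13 ± 0.08 on the log2 scale. Without astragalus replicate 2 at 500 µg/mL, 1 gene passed.

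The dose by extract test asked whether extracts differed in their change from 125 to 500 µg/mL, and 7 genes passed. An unadjusted p under 0.05 was reached by 913, near the share of 0.05 that no change would give. SLC7A11 led with adjusted p = 0.000179, its change being 0.53 for BJIKT, 0.47 for ginseng, 0.07 for astragalus, 0.13 for atractylodes and 0.87 for glycyrrhiza. SESN2, VLDLR, CHAC1, PSAT1 and PCK2, a mitochondrial enzyme of gluconeogenesis, also differed, and each had its largest rise with glycyrrhiza, at 0.45, 0.56, 0.71, 0.37 and 0.47 on the log2 scale. The count ranged from 2 without glycyrrhiza replicate 1 at 125 µg/mL to 61 without ginseng replicate 1 at 500 µg/mL.

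BJIKT and the mixture at 500 µg/mL, in sets 1 and 3, were compared directly. No set holds both, so treatment and set cannot be told apart in the values of this comparison. ATF4 and SLC7A1, an arginine importer, were 1.15-fold higher with BJIKT, each by 0.20 on the log2 scale, and CLIP3 and LRP1 by 0.46 ± 0.08 and 0.43 ± 0.09. TPH1, an enzyme of serotonin synthesis from tryptophan, and the adhesion protein TENM1 were lower by 0.62 and 0.49 on the log2 scale. ATF4 targets had 2 of 37 higher (6 adjusted over the list alone), at adjusted p = 0.00149 by camera and 0.109 with an estimated correlation. NRF2 targets had 0 of 27 called (2 higher adjusted over the list alone), at adjusted p = 0.0267 and 0.109. T-lineage factors had 0 of 24 called (5 higher adjusted over the list alone), at adjusted p = 0.000146 and 0.368. In all, 126 genes passed, 73 higher and 53 lower with BJIKT, and 0 of 6 called lists held. The count was 0 and 6 without BJIKT replicates 1 and 2, 40, 34 and 19 without mixture replicates 1, 2 and 3, and 396 with DESeq2, and 0 of 14 named genes kept their call in every such fit.

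The departure of the mixture from the sum of its 4 herbs at 125 µg/mL was called for 2233 genes, 1466 higher and 767 lower than the sum. EGR1, PRR36 and SRCAP stood above the sum by 2.53 ± 0.42, 1.94 ± 0.37 and 1.73 ± 0.26 on the log2 scale, and TCF7 and NOTCH1 by 1.09 and 1.12. SPDYE6, POLR2J2 and SPAG5-AS1 stood below it by more than 1 on the log2 scale, at -2.63, -1.69 and -1.68. Each of these 3 lost its call without 1 or more of the vehicle libraries, SPDYE6 without replicate 1 or 2 (-2.80 and -2.06), POLR2J2 without 2 or 3 (-1.62 and -1.34) and SPAG5-AS1 without 3 (-1.41), and 5 of 8 named genes kept theirs whichever library was left out. T-lineage factors had 12 of 24 above the sum (15 adjusted over the list alone), at adjusted p = 7.94e-08 by camera and 0.181 with an estimated correlation. Of the 8 called lists 0 held so. The 3 vehicle libraries, of set 1, enter this sum with 3 times the weight of the mixture's, and no set holds all 6 groups. Without vehicle replicate 1 the count was 910.

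**Figure D4:**
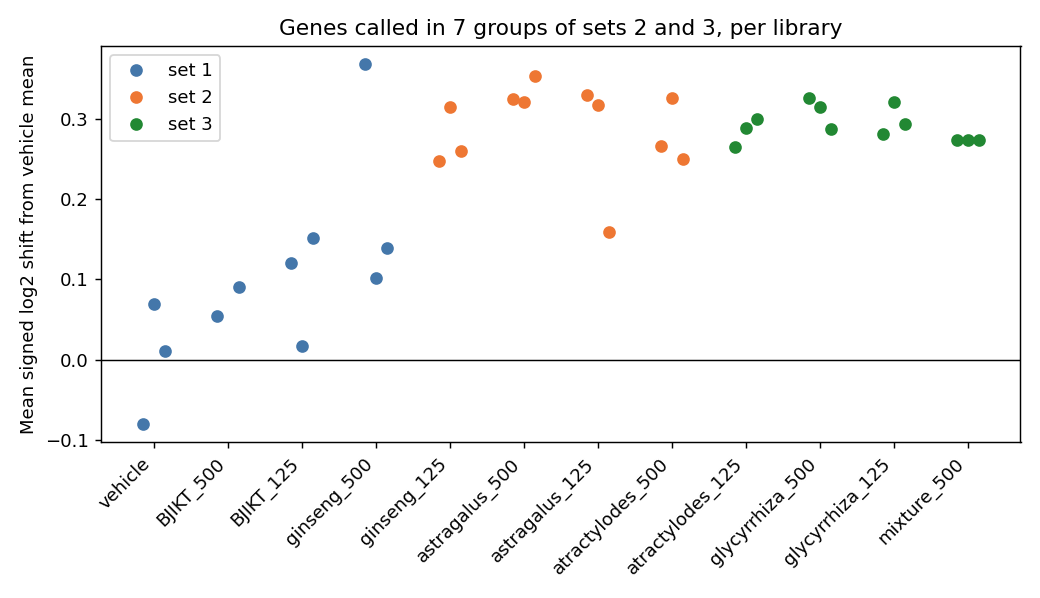
Mean shift in log2 CPM from the vehicle mean, per library, over 442 genes called in the same direction against vehicle in 7 groups of sets 2 and 3, ginseng at 125 µg/mL left out of the choice, with the sign set so that this direction is positive. Libraries of sets 2 and 3 lie between 0.159 and 0.353, and those of set 1 between -0.08 and 0.151 except ginseng replicate 1 at 500 µg/mL, at 0.368.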

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

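The tests of a difference between sets of libraries, for the genes shared by 8 groups and for the NRF2 targets, and the offsets for GC content and transcript length were chosen only after the results were seen.

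The change from 125 to 500 µg/mL differed between the 5 extracts for 7 genes in edgeR's dose by extract test. The adjusted p was 0.000179 for SLC7A11, 0.00158 for SESN2, 0.0139 for VLDLR, 0.0279 for CHAC1, 0.03 for PCK2, 0.0422 for PSAT1 and 0.0422 for LINC03040. Between the doses of glycyrrhiza, both in set 3, these genes rose by 0.87, 0.45, 0.56, 0.71, 0.47, 0.37 and 0.32 on the log2 scale. Between the doses of astragalus, both in set 2, the changes were 0.07, -0.17, 0.10, 0.05, -0.02, 0.03 and 0.23, with adjusted p of 0.492 or more. Between the doses of BJIKT, both in set 1, they were 0.53, 0.24, 0.21, 0.55, 0.15, 0.18 and 0.05. The doses of ginseng and of atractylodes lie in different sets, and differences between single pairs of extracts were not tested. LINC03040 is named because this test called it, outside the rule for named genes.

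Against vehicle, 422 genes were called in the same direction in all 8 groups of sets 2 and 3, 36 higher and 386 lower, where 5 simulations with unchanged genes and the shared vehicle gave a mean of 0. The simulations held no difference between sets, so they do not bear on one. Offsets for GC content and length left 75.4% of the median shift of the 422 genes (0.268 before, 0.202 after), which argues against these biases as the whole cause. Yet the median GC fraction was 0.395 for the genes higher and 0.55 for those lower, against 0.486 in all tested genes. The median transcript length was 5890 bases for those higher and 5686 for those lower, against 3031 in all tested genes. A difference between sets and an effect common to the herbs cannot be told apart, since vehicle lies in set 1 alone: the shift of ginseng at 125 µg/mL in set 2, measured on 442 genes called in the other 7 groups, was 69.3% as large from BJIKT at 125 µg/mL in set 1 and 28.7% as large from ginseng at 500 µg/mL in set 1 as from vehicle, on which the genes were chosen. The latter percentage leans on ginseng replicate 1 at 500 µg/mL, whose mean shift was 0.368 against 0.102 and 0.139 in the other 2. The change from 125 to 500 µg/mL over the 422 genes was 23.1% of the shift at 500 for astragalus and 2.7% for glycyrrhiza, so an effect that grows with dose stays open for the former, and one already complete at 125 µg/mL was not tested. The value for astragalus leans on replicate 3 at 125 µg/mL. Its mean shift over the 442 genes was 0.159, against 0.33 and 0.317 in replicates 1 and 2. At 500 µg/mL the 3 libraries had 0.325, 0.321 and 0.353.

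NRF2 targets were higher at 500 than at 125 µg/mL for all 5 extracts. The lowest median among the 3 extracts whose doses share a set was 0.086, for astragalus, with each held at an estimated correlation, which argues against a difference between sets as the whole cause. Offsets for GC content and length left 92.8% of the median for glycyrrhiza. A dose-dependent effect of the extracts on these genes is consistent with these values and stays a hypothesis, found and tested on the same data. For the 60 genes called between the doses of glycyrrhiza the other splits gave 0 at most, and 10 splits are too few for a share under 0.05.

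The departure of the mixture from the sum of the herbs is consistent with a difference between sets that enters through the 3 weights of the vehicle. Of the genes called, 95.9% had a sign opposite to the difference of set 2 (astragalus and atractylodes at 500 µg/mL) from set 1 (BJIKT at both doses), in libraries that do not enter the sum, and across these genes, which are not independent replicates, the correlation was -0.28. An interaction of the herbs is open beside it. Without vehicle replicate 1 the count of 2233 was 910. Of 50 splits of the same libraries drawn, the real one included, 1 gave as many genes (highest other 1), a share under 0.05. The drawn splits can mix libraries of different sets within a group, so their low counts do not exclude chance or a difference between sets.

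For the comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. Every split but the real one put libraries of both groups together. A difference of any origin then raises the spread within groups, so low counts there do not exclude chance or a difference between sets. The real count against vehicle and the highest among the other splits were 7 and 13 for BJIKT at 125 µg/mL, 762 and 181 for ginseng at 500, 1257 and 0 for ginseng at 125, 2335 and 1 for astragalus at 500, and 1256 and 735 for astragalus at 125 µg/mL. They were 1203 and 3 for atractylodes at 500, 1337 and 1 for atractylodes at 125, 2237 and 0 for glycyrrhiza at 500, 1836 and 0 for glycyrrhiza at 125, and 1817 and 2 for the mixture, whose lists numbered 13 and 8. Between doses they were 2 and 583 for ginseng, 0 and 0 for astragalus and for atractylodes, and 60 and 0 for glycyrrhiza. As many calls as the real split came in 3 splits for BJIKT at 125 µg/mL and for the ginseng doses, in all 10 for the astragalus and atractylodes doses, and in 1, the real one, for the others. The 583 genes of another split of the ginseng libraries point to a structure of the samples. BJIKT at 500 µg/mL, with 2 libraries, was not split.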

How the results depend on the processing

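Offsets for GC content and length, and the comparison within sets for gene lists, were chosen after seeing the data. Directions of all 216 named gene results and 178 list results were kept with RLE factors, no filter on low counts, the replicate block and the GC and length offsets, and those of the 216 also with DESeq2 and with only the compared groups in the fit. These results were chosen by their calls in the same libraries, so kept directions there are weak evidence. Against the other groups of the same set 19 of 169 gene and 28 of 107 list results turned. Gene calls lost were 1 with RLE factors, 2 with DESeq2, 3 without a filter, 3 with the block, 7 with the offsets and 82 with only the compared groups. List calls lost were 2, 8, 2 and 13 with RLE factors, without a filter, with the block and with the offsets, 133 with an estimated correlation and 48 with fry. Depth limits genes of low count, and the cause of changes below was not tested except where given.

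Without a filter the prior degrees of freedom of the fit became infinite, which removes the genes' own variance, and 34774 genes were tested. The counts were then 199 for BJIKT at 500 µg/mL, 344 at 125 and 1604 for ginseng at 500 against vehicle, 135, 209, 115, 140 and 188 between the doses of BJIKT, ginseng, astragalus, atractylodes and glycyrrhiza, 780 for BJIKT against the mixture and 459 for the dose by extract test. With only the compared groups in the fit, which leaves fewer samples to estimate the variance, they were 4 for BJIKT at 500, 0 at 125, 6 for ginseng at 500, 597 at 125, 1275 for astragalus at 500, 38 at 125, 505 for atractylodes at 500, 1104 for glycyrrhiza at 125 and 751 for the mixture, 4, 3, 18 and 209 between doses of BJIKT, astragalus, atractylodes and glycyrrhiza, and 905 for BJIKT against the mixture.

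DESeq2 called 77 for BJIKT at 500, 168 at 125 and 1483 for ginseng at 500, 12, 3 and 104 between doses of ginseng, atractylodes and glycyrrhiza, and 396 for BJIKT against the mixture. GC and length offsets gave 14 for BJIKT at 125, 466 for ginseng at 500 and 830 at 125, 9 and 126 between doses of ginseng and glycyrrhiza, 441 for BJIKT against the mixture and 11 for the dose by extract test. Part of the calls in the large counts were replaced. The offsets gave 1597 for astragalus at 500 µg/mL, 1212 of them among the 2335. For glycyrrhiza at 500 µg/mL they gave 2080, 1580 of them among the 2237, and for the mixture 1361, 1001 of them among the 1817. The replicate number as a block gave 5 between doses of ginseng. By mean correlation with the libraries of other groups, 15 of 35 libraries were closest to their own of the 3 replicate numbers. The median r was 0.007 between libraries of the same number and -0.009 between those of different numbers. Lists called numbered 7 for BJIKT at 500 µg/mL with an estimated correlation and 7 with fry, and 3 for the mixture with an estimated correlation.

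The share of called genes that were higher moved too. Without a filter 114 of 199 were higher for BJIKT at 500 µg/mL (43 of 47 in the main fit), 773 of 1604 for ginseng at 500 (415 of 762), and 70 of 135, 111 of 209 and 115 of 188 between the doses of BJIKT, ginseng and glycyrrhiza (11 of 11, 2 of 2 and 52 of 60). With only the compared groups in the fit 1 of 6 was higher for ginseng at 500, and 2 of 4, 0 of 3 and 139 of 209 between those doses. With DESeq2 141 of 168 were higher for BJIKT at 125 (4 of 7), and with the offsets 222 of 466 for ginseng at 500.

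Against the other groups of the same set, a different contrast that takes treated cells as reference, the counts were 15 and 0 for BJIKT at 500 and 125, 182 and 0 for ginseng, 1 and 0 for astragalus, 2 and 70 for atractylodes, 187 and 0 for glycyrrhiza and 0 for the mixture, with 7 lists for the mixture. For the groups at 0 genes, 1241 (BJIKT), 540 (ginseng), 720 (astragalus), 581 (glycyrrhiza) and 812 (mixture) had an unadjusted p under 0.05. With no change a share of 0.05 of the 17363 genes would reach it, and all but the count of BJIKT lie under that. For BJIKT, astragalus and glycyrrhiza the reference held the same extract at the other dose, and for the mixture it held some of its herbs. Effects of the extracts can therefore cancel or turn there. Turned in direction there, none of them called, were PPM1F-AS1 -0.007, PRR36 0.071 and SRCAP 0.059 for ginseng at 125, SRCAP 0.039 and TCF7 0.018 for atractylodes at 500, PRR36 0.099 for atractylodes at 125, LUCAT1 -0.215, SLC7A11 -0.244 and OSGIN1 -0.359 for glycyrrhiza at 125, and LINC00861 -0.024, PRR36 0.03, EGR1 0.063, NOTCH3 0.043, SRCAP 0.025, ADGRG1 0.03, PSAT1 -0.032, TCF7 0.018, GATA3 0.009 and NOTCH1 0.055 for the mixture. Lists whose test turned in direction, with their medians, were ATF4 -0.035 and NRF2 -0.045 for BJIKT at 125, unfolded protein response 0.015 for ginseng at 500, mitochondrially encoded -0.009, glucocorticoid 0.001 and clock 0.012 for ginseng at 125, glucocorticoid 0.014, Notch 0.046 and T-lineage 0.005 for astragalus at 125, oxidative phosphorylation -0.024, ribosomal -0.024, glucocorticoid 0.001, Notch 0.014 and T-lineage 0.018 for atractylodes at 500, clock 0.004 and Notch 0.047 for atractylodes at 125, glucocorticoid 0.013 for glycyrrhiza at 500, ATF4 -0.057, NRF2 -0.048, clock 0.007 and Notch 0.029 for glycyrrhiza at 125, and ATF4 -0.036, SREBP2 -0.007, hypoxia 0.014, glucocorticoid 0.019, clock 0, Notch 0.014 and T-lineage 0.015 for the mixture. Of these lists NRF2 for BJIKT at 125, oxidative phosphorylation and ribosomal genes for atractylodes at 500, Notch for atractylodes at 125, ATF4 and NRF2 for glycyrrhiza at 125 and ATF4 for the mixture passed camera's test there. Medians changed sign while the test kept its direction, none of them called, for Notch 0.013 with BJIKT at 500, iron -0.033 and T-lineage 0.009 with glycyrrhiza at 500, and hypoxia 0.012 with glycyrrhiza at 125.

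Leaving out each library in turn, counts ran from 9 to 46 for BJIKT at 500 (where the lone library is assumed to vary like the other groups), 0 to 160 at 125, 3 to 1987 and 243 to 1896 for ginseng at 500 and 125, 1070 to 2930 and 163 to 1968 for astragalus, 371 to 1548 and 589 to 1555 for atractylodes, 1195 to 2453 and 628 to 2224 for glycyrrhiza, and 577 to 1967 for the mixture. Between doses they ran from 0 to 3 for BJIKT, 0 to 456 for ginseng, 0 to 1 for astragalus, 0 to 0 for atractylodes and 39 to 48 for glycyrrhiza, from 0 to 40 for BJIKT against the mixture, 910 to 2744 for the departure from the sum, 2 to 61 for the dose by extract test, and 9 to 12 and 10 to 12 for lists with BJIKT at 500 and the mixture. Calls held in every such fit for 118 of 216 gene and 89 of 178 list results. For lists whose test turned in direction, medians ran from -0.014 to 0.106 for oxidative phosphorylation and -0.217 to 0.051 for mitochondrially encoded genes with BJIKT at 125, -0.001 to 0.101 for oxidative phosphorylation and -0.017 to 0.104 for ribosomal genes with atractylodes at 500, and for ribosomal genes -0.118 to -0.005 with the mixture, -0.068 to 0.034 between BJIKT doses and 0.006 to 0.087 between ginseng doses. They turned without vehicle replicate 1 in the first 4, vehicle replicate 2 for the mixture, BJIKT replicate 1 at 125 and ginseng replicate 1 at 500. Medians changed sign while the test kept its direction and lost its call for mitochondrially encoded genes with ginseng at 500 (0.008 without vehicle replicate 1) and for aryl hydrocarbon receptor targets between BJIKT doses (-0.035 without replicate 1 at 500 and -0.016 without replicate 3 at 125).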

Other observations

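Over the 18 comparisons, 11 of the 40 lists, with 3 to 32 tested members, were not called by camera in any: T-cell receptor signalling (lowest adjusted p = 0.0766), cytokines and chemokines (0.25), immune checkpoints (0.317), type I interferon response (0.179), MHC class I (0.0681), TGF-beta response (0.17), and markers of B cells (0.36), monocytes and macrophages (0.13), NK cells (0.384), epithelium (0.0737) and fibroblasts (0.236). NF-kappaB targets were called for atractylodes and glycyrrhiza at 125 µg/mL, with 4 of 19 lower in each (4 and 5 adjusted over the list alone), at adjusted p = 0.0355 and 0.0145 by camera and 0.29 and 0.163 with an estimated correlation. Early T-cell activation genes were called between the doses of glycyrrhiza, with 1 of 18 higher (3 adjusted over the list alone), a median of 0.21 and adjusted p = 0.000112, which held with an estimated correlation at 0.00769. They were also called for atractylodes at both doses and glycyrrhiza at 125 µg/mL against vehicle, between the doses of ginseng and for the departure of the mixture from the sum, and those calls were lost with an estimated correlation, at adjusted p = 0.104, 0.172, 0.165, 0.142 and 0.181. For atractylodes at both doses the direction was lower, opposite to that between the doses of glycyrrhiza. The immediate early factor EGR1 was lower than in vehicle by 0.94 with glycyrrhiza at 125 µg/mL.

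Replication-dependent histone genes had a median of 0.40 on the log2 scale for atractylodes at 500 µg/mL against vehicle, with 0 of 18 called over all genes or adjusted over the list alone, at adjusted p = 0.0205 by camera and 0.203 with an estimated correlation. The call was lost without vehicle replicate 2, at a median of 0.49, and against the other groups of set 2, at 0.10. Mitochondrially encoded genes had a median of -0.27 for the mixture against vehicle, with 2 of 13 lower (5 adjusted over the list alone), at adjusted p = 0.000233 and 0.399, and the vehicle library with the highest mitochondrial share, replicate 1 at 8.95%, weighs on that value: without it the call was lost, at a median of -0.12. Targets of TFEB, the regulator of autophagy and lysosome genes, had a median of 0.08 for BJIKT at 500 µg/mL, with 0 of 31 called (3 higher adjusted over the list alone), and held with an estimated correlation at adjusted p = 0.000824.

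The log2 changes of BJIKT and the mixture at 500 µg/mL against the shared vehicle correlated across 12376 genes at r = 0.46, where simulated unchanged groups with a shared vehicle gave 0.42, and genes are not independent replicates. The covariance was 0.00805 against 0.00452 simulated. Both called 31 genes higher and 3 lower, against 1.83 and 0.249 under independence, and 0 in opposite directions. For the mixture and glycyrrhiza at 500 µg/mL, both in set 3, r was 0.83 against 0.49 simulated, with 412 genes higher and 852 lower in both (37.6 and 84.1 under independence). For BJIKT and glycyrrhiza at 500 µg/mL r was 0.49 against 0.46 simulated, with 36 genes higher and 3 lower in both (2.19 and 0.311 under independence). Vehicle has 3 libraries and was not halved, so the shared vehicle enters each of these values.

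In edgeR's comparisons within a set, 0 genes were called between ginseng and astragalus at 125 µg/mL (set 2, with 656 at an unadjusted p under 0.05), 2 between glycyrrhiza and atractylodes at 125 µg/mL (set 3) and 6 between atractylodes and astragalus at 500 µg/mL (set 2). Against BJIKT at 125 µg/mL in set 1, the 8 groups of sets 2 and 3 had between 376 and 1644 genes called. Pairs of libraries of the same group were all farther apart than repeated counts of 1 library, with a chi-square of 2.02 to 17.99 per degree of freedom in 34 pairs. The highest value was that of vehicle replicates 1 and 2. Vehicle replicates 1 and 3 had 10.86, and replicates 2 and 3 had 3.58, so replicate 1 stood apart in the only control group. Values reached 17.34 in BJIKT at 125 µg/mL and 14.85 in ginseng at 500 µg/mL.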
